A study of Homo sapiens with 18 samples.

How the data were processed

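Gene and exon levels of 3 human myeloid leukaemia cell lines, HL60, THP-1 and U937, were measured on Affymetrix human exon arrays from biotin-labelled cDNA of total RNA. Per the labels, cells were treated for 3 days with 30 nM phorbol 12-myristate 13-acetate (PMA), an activator of protein kinase C, or with its vehicle dimethyl sulfoxide (DMSO) at a 1000 fold dilution. The 18 arrays form 6 groups of 3. The labels number the arrays of each group but do not say whether they come from separate cultures, so every p-value measures only the spread between these samples.

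Per the submitters' processing notes, the arrays were processed with Affymetrix Expression Console, whose version was not stated. The values deposited by the authors are exon-level core probe-set values on the log2 scale, from 0.58 to 14.4. The background correction, normalization and summary method are not given in the sources used here. All 18 columns of values were used as deposited, without further normalization. Array medians ran from 6.18 (U937 PMA 2) to 6.95 (U937 DMSO 1). Arrays of one line shared 39 to 116 exactly tied values, with the U937 arrays numbered 2 left aside, against at most 7 between lines. The U937 arrays numbered 2, DMSO and PMA, shared at most 5 with any array. The arrays therefore appear to have been normalized in separate sets. The U937 PMA 2 array held 83228 distinct values, against 214471 to 220516 in the others. Within groups, Pearson correlations between arrays over all probe sets ran from 0.931 to 0.978. For arrays no depth is given, and their number limits the precision.

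Of 287329 probe sets, the annotation of the platform gave 261273 exactly 1 gene symbol, 9155 several and 16901 none. Of the 16941 symbols, 14546 were current in RefSeq (GRCh38.p14, used for names alone), 2260 were older names that were updated and 135 were kept. Probe-set positions and exon numbers were not used here, and no genome build of the array is given in the sources used here. A gene's value was the mean of its probe sets with 1 symbol, for the 16267 genes with at least 3. Exon usage was tested on 175116 probe sets in 11976 genes. These were probe sets with 1 symbol whose mean over the 18 arrays lay above the 30th percentile (5.17 log2), in genes with at least 5 of them.

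Gene values were compared with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8) in a single fit of 6 group means, with 12 residual and 17.06 total degrees of freedom after variance moderation. Contrasts were PMA against DMSO in each line, the pairwise differences of these effects between lines, and the lines against each other with DMSO. Two-sided p-values from limma's moderated test were adjusted by the Benjamini-Hochberg method over all genes, and genes with an adjusted p under 0.05 were called. The median SE was 0.226 log2 for a PMA effect and 0.320 for a difference of effects. Exon usage was tested with limma's diffSplice, which sets the log2 change of a probe set against that of the other probe sets of its gene. A probe set was called at an adjusted p under 0.05 and a difference of at least 1 log2 unit. A positive difference means that the probe set rose more, or fell less, than the rest of its gene. It takes the spread from all probe sets of a gene as if they were independent, so its p-values do not rest on the number of arrays alone. As an alternative, limma was run per probe set on the splicing index, the probe-set value minus the gene mean.

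The gene lists were monocyte and macrophage surface markers, macrophage lipid and scavenging genes, primary granule proteins, cytokines and chemokines, NF-kappaB targets and regulators, matrix proteases and their inhibitors, integrins and adhesion, lysosome, NADPH oxidase, MHC class II antigen presentation, interferon-stimulated genes, DNA replication and G1/S, mitosis and G2/M, CDK inhibitors, MYC and ribosome biogenesis, AP-1, EGR and immediate early genes, myeloid transcription factors, protein kinase C family, splicing regulators, glycolysis, cholesterol synthesis, oxidative phosphorylation, T and NK cell markers, B cell markers, erythroid and megakaryocyte markers, epithelial and fibroblast markers, and dendritic cell and osteoclast markers. These 27 lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over all 81 tests, and again with a correlation estimated per list. A further list, genes with known regulated exons, served only the exon usage test: the share of its genes with a called probe set was set against that of all tested genes by Fisher's exact test, two-sided. It was also set against 10000 random lists matched in the number of probe sets per gene, one-sided.

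Genes named in the text follow a fixed rule. It takes, per line, the 10 largest increases and decreases among called genes whose 3 PMA arrays all lay beyond the 3 DMSO arrays, and up to 4 genes per list with the largest change. To these it adds 10 fixed genes, the 5 largest differences in each direction per pair of lines, the same for the lines with DMSO, and the 10 largest shared changes in each direction. For exon usage it takes the 8 largest calls per line whose splicing index separates the 3 PMA from the 3 DMSO arrays, and the 8 largest shared calls, in each case at most 1 per gene, and the calls in 10 fixed genes. Of the genes so named, 1 further gene is not reported here. The tests, thresholds, lists and naming rule were chosen before the data were examined, except those named below as chosen after seeing the data.

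Deviations of same-numbered DMSO and PMA arrays from their group means correlated at 0.28 to 0.79, so the numbers were taken to pair the samples. Different numbers correlated at -0.65 to 0.44, in some cases above the same number: DMSO 1 with PMA 2 in THP-1 (0.44 against 0.40 for PMA 1) and DMSO 2 with PMA 1 in U937 (0.33 against 0.28 for PMA 2). In each of these cases both arrays belong to the same of 2 sets of arrays found from these deviations. A replicate block (cell line by array number) was tried as an alternative. Others were quantile normalization, centring each array on its median, median polish, filters on dim genes or probe sets, an intensity trend in the variance, only the arrays compared, only genes with a change within -1 to 1, no minimum difference, and leaving out each array in turn. Chosen after seeing the data were the random lists, the list tests on differences between lines, families of genes by the root of their symbol, a block for the 2 sets of arrays, the correlation of PMA effects between these sets, the test of array scaling, leaving out both U937 arrays numbered 2, and an estimated correlation with the replicate block.

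The pipeline was tested on simulated data with 50 genes or probe sets planted at each size in HL60. The gene-level test recovered 4%, 48%, 92% and 98% of changes of 0.5, 1, 2 and 3 log2 units. For exon usage, diffSplice recovered 2%, 8%, 72% and 92%, and the splicing index 0%, 14%, 68% and 86%. Where nothing was planted, diffSplice called 484, 518 and 527 probe sets in HL60, THP-1 and U937, and the splicing index 3, 0 and 0.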

Results

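With 3 days of PMA, the secreted phosphoprotein SPP1 rose in HL60, THP-1 and U937 by 6.31 ± 0.33, 8.38 ± 0.33 and 7.23 ± 0.33 log2 units, and the progenitor transcription factor MYB fell by 5.47 ± 0.32, 2.94 ± 0.32 and 3.01 ± 0.32. Changes (3 PMA, 3 DMSO arrays per line) are in log2 units ± SE pooled over all groups. Levels are means ± SD of 3 arrays. Changes from levels below 5.17, the 30th percentile of probe sets, as of SPP1, RGS1 and DCSTAMP, are approximate. All p-values of genes and probe sets are from limma and adjusted over all genes or probe sets tested, those of lists are from limma's camera. Since the labels do not say whether replicates are separate cultures, the p-values measure only the spread between these samples. The 10 largest increases and decreases named per line were taken from genes in which all 3 PMA arrays lay beyond all 3 DMSO arrays.

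In HL60, the cell fusion receptor DCSTAMP, needed for multinucleated osteoclasts and giant cells, rose by 8.57 ± 0.33, from 3.61 ± 0.24 to 12.17 ± 0.11. Myeloperoxidase (MPO), the main enzyme of primary granules, fell by 5.88 ± 0.19, from 12.60 ± 0.10 to 6.71 ± 0.23. The inhibitor of cyclin-dependent kinases CDKN1A rose by 3.79 ± 0.18 and MYC fell by 1.93 ± 0.32. The integrin chain ITGAM, part of the complement receptor of phagocytes, rose by 3.57 ± 0.37, while the lipopolysaccharide co-receptor CD14 fell by 1.13 ± 0.24 (adjusted p = 0.00184). Of 16267 genes, limma called 2007 higher and 1738 lower, 3745 in all, of which 1302 and 1092 changed at least 2-fold.

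The other largest increases in HL60 were of the membrane proteins EMP1 (6.91 ± 0.26), CD52 (6.9 ± 0.42) and TM4SF19 (6.40 ± 0.32), the tetraspanin CD9 (6.84 ± 0.39) and the adhesion receptor CD226 (6.81 ± 0.24). They also included RGS1 (6.85 ± 0.50), a regulator of G protein signalling, the protease inhibitor A2M (6.70 ± 0.35), GALNT12 (6.43 ± 0.23), an enzyme of mucin-type glycosylation, and SPP1 (6.31 ± 0.33). The largest decrease was of SERPINB10 (-6.47 ± 0.23), a serpin of haematopoietic cells. MYB (-5.47 ± 0.32), the calcium-binding S100A8 (-4.92 ± 0.56), NUCB2 (-4.78 ± 0.42), PLAC8 (-4.52 ± 0.32) and ANKRD22 (-4.29 ± 0.17) fell too. So did the proliferation genes TOP2A (-4.99 ± 0.27), PCLAF (-4.50 ± 0.54) and CENPF (-4.30 ± 0.29). Interleukin IL1B rose by 5.32 ± 0.33, the gelatinase MMP9 by 2.92 ± 0.22 and the hyaluronan receptor CD44 by 1.27 ± 0.27. The chemokine CXCL8 rose by 2.20 ± 0.59 (adjusted p = 0.00993), but not without the HL60 PMA 1 array (1.64, adjusted p = 0.0613).

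Monocyte and macrophage surface markers went up in HL60 (11 higher, 3 lower and 7 not called of 21), among them ITGAX (4.30 ± 0.30), MERTK (4.28 ± 0.25) and CD36 (4.27 ± 0.44). Surface markers had median 1.08 (adjusted p = 0.000893 and adjusted p = 0.402 with an estimated correlation), with 12 and 3 adjusted over the list alone. Macrophage lipid and scavenging genes went up (16 higher, 0 lower and 3 not called of 19), with the oxidized lipoprotein receptor OLR1 at 4.52 ± 0.37 and GPNMB at 3.84 ± 0.30. Lipid genes had median 1.99 (adjusted p = 1.37e-11 and adjusted p = 0.0968 with an estimated correlation), with 16 and 0 adjusted over the list alone. Primary granule proteins went down (0 higher, 10 lower and 2 not called of 12), including the elastase ELANE (-3.83 ± 0.21), cathepsin G (CTSG, -3.36 ± 0.49) and PRTN3 (-3.26 ± 0.29). Granule proteins had median -2.34 (adjusted p = 2.2e-13 and adjusted p = 0.0406 with an estimated correlation), with 0 and 10 adjusted over the list alone. Cytokines and chemokines went up (14 higher, 0 lower and 9 not called of 23), with CSF1 (5.87 ± 0.28), the macrophage growth factor, IL1RN (5.76 ± 0.36) and CCL22 (4.97 ± 0.27). Cytokines and chemokines had median 1.99 (adjusted p = 1.96e-08 and adjusted p = 0.126 with an estimated correlation), with 14 and 0 adjusted over the list alone. NF-kappaB targets and regulators went up (10 higher, 1 lower and 7 not called of 18), for example ICAM1 (3.11 ± 0.22), IER3 (2.76 ± 0.32) and CD83 (2.07 ± 0.26). NF-kappaB genes had median 1.03 (adjusted p = 0.000708 and adjusted p = 0.336 with an estimated correlation), with 11 and 1 adjusted over the list alone. Matrix proteases and their inhibitors went up (13 higher, 2 lower and 5 not called of 20), led by MMP7 (6.27 ± 0.49), TIMP1 (4.66 ± 0.19) and MMP19 (3.79 ± 0.21). Matrix proteases had median 1.96 (adjusted p = 3.56e-06 and adjusted p = 0.208 with an estimated correlation), with 13 and 2 adjusted over the list alone. Integrins and adhesion genes went up (18 higher, 2 lower and 5 not called of 25), with ITGB7 at 4.63 ± 0.27 and ITGA3 at 3.51 ± 0.31. Adhesion genes had median 1.87 (adjusted p = 2.18e-09 and adjusted p = 0.183 with an estimated correlation), with 20 and 2 adjusted over the list alone. Lysosome genes went up (14 higher, 1 lower and 10 not called of 25), with the cathepsins CTSL (5.14 ± 0.35), CTSH (2.79 ± 0.25) and CTSB (2.50 ± 0.20). Lysosome genes had median 0.92 (adjusted p = 4.4e-06 and adjusted p = 0.295 with an estimated correlation), with 14 and 1 adjusted over the list alone.

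Interferon-stimulated genes went up in HL60 (8 higher, 1 lower and 12 not called of 21), with IFIT3 (2.52 ± 0.34), IFI6 (2.26 ± 0.21) and OAS1 (1.70 ± 0.21). Interferon genes had median 0.44 (adjusted p = 0.0096 and adjusted p = 0.428 with an estimated correlation), with 10 and 1 adjusted over the list alone. Genes of DNA replication and G1/S went down (0 higher, 32 lower and 1 not called of 33), including the helicase subunit MCM6 (-3.35 ± 0.28) and CDC45 (-3.22 ± 0.27). Replication genes had median -2.31 (adjusted p = 1.04e-33 and adjusted p = 0.0406 with an estimated correlation), with 0 and 32 adjusted over the list alone. Genes of mitosis and G2/M went down (0 higher, 29 lower and 2 not called of 31), including ASPM (-4.05 ± 0.28) and DLGAP5 (-4.02 ± 0.32). Mitosis genes had median -2.97 (adjusted p = 5.49e-35 and adjusted p = 0.0406 with an estimated correlation), with 0 and 29 adjusted over the list alone. MYC and ribosome biogenesis genes went down (0 higher, 16 lower and 5 not called of 21), with UTP20 at -1.96 ± 0.28 and NOLC1 at -1.68 ± 0.23. Ribosome biogenesis genes had median -1.08 (adjusted p = 2.49e-09 and adjusted p = 0.0968 with an estimated correlation), with 0 and 16 adjusted over the list alone. AP-1, EGR and immediate early genes went up (19 higher, 0 lower and 6 not called of 25), with EGR2 (6.01 ± 0.26), JUN (4.52 ± 0.30), ATF3 (3.34 ± 0.26) and the phosphatase DUSP5 (3.25 ± 0.19). Immediate early genes had median 1.24 (adjusted p = 1.29e-12 and adjusted p = 0.0836 with an estimated correlation), with 20 and 0 adjusted over the list alone. Splicing regulators went down (1 higher, 17 lower and 30 not called of 48), among them PTBP2 (-1.91 ± 0.24), whereas RBFOX2 rose by 1.27 ± 0.24. Splicing regulators had median -0.49 (adjusted p = 1.68e-06 and adjusted p = 0.366 with an estimated correlation), with 1 and 19 adjusted over the list alone. Cholesterol synthesis genes went up (8 higher, 1 lower and 9 not called of 18), with MSMO1 (2.91 ± 0.43) and STARD4 (2.61 ± 0.32). Cholesterol genes had median 1.07 (adjusted p = 0.00644 and adjusted p = 0.618 with an estimated correlation), with 9 and 1 adjusted over the list alone. Dendritic cell and osteoclast markers went up (5 higher, 1 lower and 11 not called of 17), with CD1C (2.19 ± 0.28) and CD1A (1.64 ± 0.29). Dendritic markers had median 0.37 (adjusted p = 0.0487 and adjusted p = 0.626 with an estimated correlation), with 5 and 1 adjusted over the list alone. That call was lost with quantile normalization (adjusted p = 0.0685), median polish (adjusted p = 0.0627), the replicate block (adjusted p = 0.0546), genes above the 30th percentile (adjusted p = 0.329) and without both U937 arrays numbered 2 (adjusted p = 0.0529).

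Not called in HL60 was NADPH oxidase (1 higher, 1 lower and 3 not called of 5, 1 and 1 adjusted over the list alone, median 0.11, adjusted p = 0.705), with RAC2 at 1.49 ± 0.23 and NCF4 at -1.30 ± 0.30. MHC class II antigen presentation was not called either (4 higher, 1 lower and 6 not called of 11, 4 and 1 adjusted over the list alone, median 0.18, adjusted p = 0.339), with IFI30 at 2.62 ± 0.27 and CD74 at -1.58 ± 0.31. CDK inhibitors (3 higher, 2 lower and 3 not called of 8, 3 and 2 adjusted over the list alone, median 0.17, adjusted p = 0.271) held CDKN1A, CDKN2B (2.21 ± 0.18) and CDKN2C (-1.21 ± 0.29). Myeloid transcription factors (4 higher, 3 lower and 17 not called of 24, 5 and 3 adjusted over the list alone, median 0.28, adjusted p = 0.66) held IRF8 (-2.84 ± 0.43), a factor of monocyte development, ID2 (2.64 ± 0.46) and CEBPB (2.34 ± 0.18), and their mean lay 0.08 below that of other genes despite the positive median. The protein kinase C family (6 higher, 1 lower and 11 not called of 18, 6 and 1 adjusted over the list alone, median 0.03, adjusted p = 0.66), whose median turned to -0.05 with quantile normalization, held the Ras family exchange factors RASGRP3 (3.30 ± 0.35), RASGRP1 (2.25 ± 0.22) and RASGRP2 (-2.37 ± 0.15). Glycolysis (6 higher, 2 lower and 13 not called of 21, 6 and 2 adjusted over the list alone, median 0.05, adjusted p = 0.339), at a median of -0.00 with centred arrays, held ENO2 (3.13 ± 0.25), PFKFB4 (2.75 ± 0.30) and the glucose transporter SLC2A3 (2.24 ± 0.30). Oxidative phosphorylation was not called (1 higher, 0 lower and 23 not called of 24, 0 and 0 adjusted over the list alone, median -0.14, adjusted p = 0.379), although with the replicate block COX5A (adjusted p = 0.0186), ATP5PO (adjusted p = 0.0206) and NDUFV1 (adjusted p = 0.0185) were lower (list adjusted p = 0.258). Neither were T and NK cell markers (0 higher, 1 lower and 14 not called of 15, 0 and 1 adjusted over the list alone, median 0.19, adjusted p = 0.759). The same held for B cell markers (2 higher, 0 lower and 8 not called of 10, 2 and 0 adjusted over the list alone, median 0.24, adjusted p = 0.215). Epithelial and fibroblast markers were not called (0 higher, 0 lower and 14 not called of 14, 0 and 0 adjusted over the list alone, median 0.12, adjusted p = 0.721). NKG7 fell by 1.58 ± 0.19, and the mean of the T and NK cell markers minus that of other genes was -0.00. Erythroid and megakaryocyte markers (3 higher, 0 lower and 10 not called of 13, 3 and 0 adjusted over the list alone, median 0.05, adjusted p = 0.339), with a median of -0.01 under quantile normalization, held PPBP (2.75 ± 0.61), ITGB3 (1.97 ± 0.29) and TAL1 (0.94 ± 0.19).

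In THP-1, SPP1 rose by 8.38 ± 0.33, RGS1 by 8.05 ± 0.50, the collagenase MMP1 by 7.22 ± 0.64 and the scavenger receptor MSR1 by 7.19 ± 0.28. CD14 rose by 3.84 ± 0.24, CDKN1A by 3.17 ± 0.18 and ITGAM by 2.98 ± 0.37, and MPO fell by 0.81 ± 0.19 (adjusted p = 0.00399). The limma test called 1524 genes higher and 2144 lower, 3668 in all, of which 924 and 1199 changed at least 2-fold. Under the replicate block 5646 were called. Of those called the share lower was 58.5% as deposited, 49.9% with quantile normalization and 48.3% with centred arrays.

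The other large increases in THP-1 were of A2M (6.79 ± 0.35), the fatty acid binding protein FABP4 (6.66 ± 0.68), IL1B (6.54 ± 0.33), TM4SF19 (6.25 ± 0.32), EMP1 (5.90 ± 0.26) and DDIT4L (5.54 ± 0.23), a relative of a stress-induced inhibitor of mTOR. The orphan receptor GPR160 fell most (-3.89 ± 0.49), with CTSG (-3.78 ± 0.49), the ion channel MCOLN2 (-3.63 ± 0.40), MS4A6A (-3.56 ± 0.38) and the monocyte chemokine receptor CCR2 (-3.55 ± 0.40). LAMP5 (-3.51 ± 0.36), the chaperone HSPA4L (-3.34 ± 0.34), NCAM2 (-3.30 ± 0.26), LRRCC1 (-3.23 ± 0.31) and the defensin DEFB1 (-3.22 ± 0.49) fell as well. MMP9 rose by 4.55 ± 0.22, CXCL8 by 2.49 ± 0.59 (adjusted p = 0.00452) and CD44 by 1.11 ± 0.27. MYC fell by 1.05 ± 0.32 (adjusted p = 0.0226). That call was lost with median polish (adjusted p = 0.0665), with only the arrays of the line (adjusted p = 0.0836), and without THP-1 DMSO 1 (adjusted p = 0.122), DMSO 2 (adjusted p = 0.117), PMA 1 (adjusted p = 0.0523) or PMA 3 (adjusted p = 0.104). Without THP-1 DMSO 2 the genes lower numbered 1375.

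Monocyte and macrophage surface markers went up in THP-1 (11 higher, 1 lower and 9 not called of 21), with MSR1 and CD14. Surface markers had median 0.81 (adjusted p = 2.32e-08 and adjusted p = 0.141 with an estimated correlation), with 11 and 1 adjusted over the list alone. Macrophage lipid and scavenging genes went up (12 higher, 1 lower and 6 not called of 19), with FABP4 and MSR1. Lipid genes had median 1.33 (adjusted p = 6.21e-09 and adjusted p = 0.141 with an estimated correlation), with 13 and 1 adjusted over the list alone. Primary granule proteins went down (0 higher, 7 lower and 5 not called of 12), led by CTSG and ELANE (-2.77 ± 0.21). Granule proteins had median -0.94 (adjusted p = 2.76e-05 and adjusted p = 0.126 with an estimated correlation), with 0 and 7 adjusted over the list alone. Cytokines and chemokines went up (8 higher, 0 lower and 15 not called of 23), with CCL20 (3.87 ± 0.59) and TGFB1 (2.62 ± 0.19). Cytokines and chemokines had median 0.49 (adjusted p = 0.00026 and adjusted p = 0.321 with an estimated correlation), with 8 and 0 adjusted over the list alone. NF-kappaB targets and regulators went up (9 higher, 0 lower and 9 not called of 18), with ICAM1 at 3.23 ± 0.22. NF-kappaB genes had median 0.63 (adjusted p = 0.000392 and adjusted p = 0.319 with an estimated correlation), with 11 and 0 adjusted over the list alone. Matrix proteases and their inhibitors went up (15 higher, 1 lower and 4 not called of 20), with the urokinase receptor PLAUR at 3.51 ± 0.21. Matrix proteases had median 1.82 (adjusted p = 3.93e-12 and adjusted p = 0.0869 with an estimated correlation), with 15 and 1 adjusted over the list alone. Integrins and adhesion genes went up (21 higher, 1 lower and 3 not called of 25), with ITGB7 (4.20 ± 0.27) and ITGB5 (4.14 ± 0.28). Adhesion genes had median 1.65 (adjusted p = 4.17e-15 and adjusted p = 0.0968 with an estimated correlation), with 21 and 1 adjusted over the list alone. Lysosome genes went up (16 higher, 0 lower and 9 not called of 25). Lysosome genes had median 0.99 (adjusted p = 1.14e-09 and adjusted p = 0.145 with an estimated correlation), with 18 and 0 adjusted over the list alone. NADPH oxidase genes went up (2 higher, 0 lower and 3 not called of 5), with the catalytic subunit CYBB at 3.34 ± 0.28, but not without both U937 arrays numbered 2 (adjusted p = 0.0573). Oxidase genes had median 0.36 (adjusted p = 0.0242 and adjusted p = 0.16 with an estimated correlation), with 2 and 0 adjusted over the list alone.

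Interferon-stimulated genes went up in THP-1 (7 higher, 2 lower and 12 not called of 21), with IFI6 (3.27 ± 0.21) and OAS1 (2.6 ± 0.21), but not with quantile normalization (adjusted p = 0.0685) or without both U937 arrays numbered 2 (adjusted p = 0.0636). Interferon genes had median 0.16 (adjusted p = 0.0195 and adjusted p = 0.473 with an estimated correlation), with 8 and 2 adjusted over the list alone. DNA replication and G1/S genes went down (0 higher, 29 lower and 4 not called of 33), with RFC3 at -2.30 ± 0.20. Replication genes had median -1.40 (adjusted p = 6.88e-21 and adjusted p = 0.0672 with an estimated correlation), with 0 and 31 adjusted over the list alone. Mitosis and G2/M genes went down (0 higher, 31 lower and 0 not called of 31), with the kinase TTK at -3.0 ± 0.38. Mitosis genes had median -2.08 (adjusted p = 4.93e-28 and adjusted p = 0.0672 with an estimated correlation), with 0 and 31 adjusted over the list alone. MYC and ribosome biogenesis genes went down (0 higher, 14 lower and 7 not called of 21). Ribosome biogenesis genes had median -0.97 (adjusted p = 5.19e-07 and adjusted p = 0.141 with an estimated correlation), with 0 and 14 adjusted over the list alone. AP-1, EGR and immediate early genes went up (16 higher, 0 lower and 9 not called of 25), with MAF (2.82 ± 0.17), a macrophage transcription factor, and DUSP6 (2.90 ± 0.21). Immediate early genes had median 1.38 (adjusted p = 6.22e-14 and adjusted p = 0.0717 with an estimated correlation), with 18 and 0 adjusted over the list alone. Splicing regulators went down (0 higher, 13 lower and 35 not called of 48), with MBNL3 (-1.85 ± 0.24), PTBP2 (-1.53 ± 0.24), MBNL1 (-1.43 ± 0.26) and ESRP1 (-1.40 ± 0.17). Splicing regulators had median -0.56 (adjusted p = 5.19e-05 and adjusted p = 0.442 with an estimated correlation), with 0 and 18 adjusted over the list alone. Dendritic cell and osteoclast markers went up (7 higher, 1 lower and 9 not called of 17), with the lectin CD209 (2.47 ± 0.42) up and FLT3 (-1.46 ± 0.24) down. Dendritic markers had median 0.36 (adjusted p = 0.00253 and adjusted p = 0.432 with an estimated correlation), with 7 and 1 adjusted over the list alone.

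Other lists were not called in THP-1. MHC class II antigen presentation (3 higher, 2 lower and 6 not called of 11, 3 and 3 adjusted over the list alone, median 0.09, adjusted p = 0.379) held IFI30 (4.53 ± 0.27), and was called among genes above the 30th percentile (adjusted p = 0.0106). CDK inhibitors (2 higher, 2 lower and 4 not called of 8, 2 and 2 adjusted over the list alone, median 0.32, adjusted p = 0.343) held CDKN1A. Myeloid transcription factors (6 higher, 6 lower and 12 not called of 24, 6 and 7 adjusted over the list alone, median 0.07, adjusted p = 0.886), whose mean was -0.09 despite a positive median, held IRF8 (-2.54 ± 0.43), KLF4 (1.85 ± 0.36) and GFI1 (-1.38 ± 0.26). The protein kinase C family (2 higher, 4 lower and 12 not called of 18, 2 and 6 adjusted over the list alone, median -0.07, adjusted p = 0.267) had a median of 0.02 with centred arrays. Glycolysis (4 higher, 1 lower and 16 not called of 21, 4 and 1 adjusted over the list alone, median -0.07, adjusted p = 0.558), with LDHA at -0.78 ± 0.16, had a mean of 0.17 against its negative median, which turned to 0.01 with centred arrays. Cholesterol synthesis (1 higher, 0 lower and 17 not called of 18, 1 and 0 adjusted over the list alone, median -0.02, adjusted p = 0.976) had a median of 0.05 with quantile normalization and a mean 0.02 above other genes. Oxidative phosphorylation (0 higher, 0 lower and 24 not called of 24, 0 and 0 adjusted over the list alone, median -0.24, adjusted p = 0.343) was not called, although with the replicate block NDUFS3 (adjusted p = 0.0307), NDUFA9 (adjusted p = 0.0467) and NDUFV1 (adjusted p = 0.0297) were lower (list adjusted p = 0.173). T and NK cell markers (0 higher, 1 lower and 14 not called of 15, 0 and 1 adjusted over the list alone, median 0.25, adjusted p = 0.267) were not called. Erythroid and megakaryocyte markers (2 higher, 0 lower and 11 not called of 13, 2 and 0 adjusted over the list alone, median 0.12, adjusted p = 0.0711) were not called. Neither were B cell markers (1 higher, 0 lower and 9 not called of 10, 1 and 0 adjusted over the list alone, median 0.15, adjusted p = 0.0899), with the lectin CD22 at 3.80 ± 0.15, or epithelial and fibroblast markers (1 higher, 0 lower and 13 not called of 14, 1 and 0 adjusted over the list alone, median 0.16, adjusted p = 0.161), with the receptor PDGFRA at 1.55 ± 0.20.

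In U937, SPP1 rose by 7.23 ± 0.33, from 5.00 ± 0.28 to 12.23 ± 0.37, RGS1 by 6.42 ± 0.50 and TDO2, an enzyme that degrades tryptophan, by 6.27 ± 0.58. CD14 rose by 1.46 ± 0.24, ITGAM by 2.87 ± 0.37 and CDKN1A by 3.36 ± 0.18, and MYC fell by 1.89 ± 0.32. MPO, low before treatment, was not called (0.20 ± 0.19, adjusted p = 0.61). The limma test called 894 genes higher and 2678 lower, 3572 in all, of which 561 and 1636 changed at least 2-fold. The replicate block gave 5403. The share lower was 75% as deposited, 51.7% with quantile normalization, 49.6% with centred arrays, and 49.7% without U937 PMA 2, when 1895 were higher and 1873 lower.

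DCSTAMP (6.18 ± 0.33), MMP1 (5.94 ± 0.64), the water and glycerol channel AQP9 (5.90 ± 0.44), MMP7 (5.86 ± 0.49), CD52 (5.7 ± 0.42), GPR34 (5.69 ± 0.43) and TM4SF19 (5.67 ± 0.32) also rose in U937. The granule protease CTSG fell most (-5.06 ± 0.49), followed by LAMP5 (-4.17 ± 0.36), PLAC8 (-3.67 ± 0.32), ERCC6L (-3.11 ± 0.30), HSPA4L (-3.10 ± 0.34) and CLECL1 (-3.07 ± 0.25). NUCB2 (-3.06 ± 0.42), MYB (-3.01 ± 0.32) and the replication genes DTL (-3.05 ± 0.23) and GINS2 (-3.02 ± 0.30) fell too. MMP9 rose by 4.44 ± 0.22, IL1B by 3.97 ± 0.33, CXCL8 by 2.95 ± 0.59 (adjusted p = 0.00124) and CD44 by 1.16 ± 0.27.

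Monocyte and macrophage surface markers went up in U937 (13 higher, 0 lower and 8 not called of 21), with ITGAX (4.85 ± 0.30), VSIG4 (3.87 ± 0.44) and the haemoglobin receptor CD163 (3.33 ± 0.38). Surface markers had median 1.54 (adjusted p = 3.93e-13 and adjusted p = 0.0836 with an estimated correlation), with 13 and 1 adjusted over the list alone. Macrophage lipid and scavenging genes went up (11 higher, 0 lower and 8 not called of 19), with CHI3L1 at 3.09 ± 0.29. Lipid genes had median 1.46 (adjusted p = 9.27e-10 and adjusted p = 0.126 with an estimated correlation), with 11 and 0 adjusted over the list alone. Cytokines and chemokines went up (12 higher, 0 lower and 11 not called of 23), with CCL7 at 4.98 ± 0.47. Cytokines and chemokines had median 0.97 (adjusted p = 4.06e-14 and adjusted p = 0.0672 with an estimated correlation), with 16 and 0 adjusted over the list alone. NF-kappaB targets and regulators went up (13 higher, 0 lower and 5 not called of 18), with IER3 (4.07 ± 0.32) and TRAF1 (2.38 ± 0.28). NF-kappaB genes had median 0.91 (adjusted p = 3.99e-10 and adjusted p = 0.0892 with an estimated correlation), with 13 and 0 adjusted over the list alone. Matrix proteases and their inhibitors went up (13 higher, 0 lower and 7 not called of 20), led by MMP1, MMP7 and MMP9. Matrix proteases had median 1.29 (adjusted p = 1.99e-15 and adjusted p = 0.0672 with an estimated correlation), with 13 and 0 adjusted over the list alone. Integrins and adhesion genes went up (14 higher, 2 lower and 9 not called of 25). Adhesion genes had median 1.16 (adjusted p = 7.12e-12 and adjusted p = 0.137 with an estimated correlation), with 15 and 2 adjusted over the list alone. Lysosome genes went up (7 higher, 1 lower and 17 not called of 25). Lysosome genes had median 0.55 (adjusted p = 1.64e-07 and adjusted p = 0.208 with an estimated correlation), with 7 and 1 adjusted over the list alone. NADPH oxidase genes went up (2 higher, 0 lower and 3 not called of 5), with CYBB at 2.48 ± 0.28, but not without both U937 arrays numbered 2 (adjusted p = 0.0511). Oxidase genes had median 0.33 (adjusted p = 0.00937 and adjusted p = 0.126 with an estimated correlation), with 2 and 0 adjusted over the list alone. MHC class II antigen presentation went up (4 higher, 1 lower and 6 not called of 11), but not with quantile normalization (adjusted p = 0.0662), with median polish (adjusted p = 0.0693) or without both U937 arrays numbered 2 (adjusted p = 0.127). Class II genes had median 0.08 (adjusted p = 0.0488 and adjusted p = 0.549 with an estimated correlation), with 4 and 1 adjusted over the list alone.

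Interferon-stimulated genes went up in U937 (8 higher, 2 lower and 11 not called of 21), although HERC5 fell by 1.54 ± 0.24. Interferon genes had median 0.56 (adjusted p = 9.39e-05 and adjusted p = 0.208 with an estimated correlation), with 9 and 2 adjusted over the list alone. DNA replication and G1/S genes went down (0 higher, 31 lower and 2 not called of 33), and so did mitosis and G2/M genes (0 higher, 30 lower and 1 not called of 31). Replication genes had median -2.09 (adjusted p = 2.76e-29 and adjusted p = 0.0406 with an estimated correlation), with 0 and 33 adjusted over the list alone. Mitosis genes had median -1.88 (adjusted p = 3.15e-23 and adjusted p = 0.0672 with an estimated correlation), with 0 and 31 adjusted over the list alone. MYC and ribosome biogenesis genes went down (0 higher, 18 lower and 3 not called of 21), with NOLC1 at -2.39 ± 0.23. Ribosome biogenesis genes had median -1.55 (adjusted p = 7.12e-12 and adjusted p = 0.0717 with an estimated correlation), with 0 and 21 adjusted over the list alone. AP-1, EGR and immediate early genes went up (17 higher, 0 lower and 8 not called of 25). Immediate early genes had median 0.96 (adjusted p = 1.04e-15 and adjusted p = 0.0672 with an estimated correlation), with 17 and 0 adjusted over the list alone. Splicing regulators went down (1 higher, 25 lower and 22 not called of 48), with MBNL3 at -1.51 ± 0.24, while HNRNPLL, which represses exons of PTPRC, rose by 2.34 ± 0.41. Splicing regulators had median -0.77 (adjusted p = 6.84e-06 and adjusted p = 0.399 with an estimated correlation), with 1 and 29 adjusted over the list alone. Dendritic cell and osteoclast markers went up (3 higher, 1 lower and 13 not called of 17), with DCSTAMP. Dendritic markers had median 0.21 (adjusted p = 0.000884 and adjusted p = 0.397 with an estimated correlation), with 4 and 1 adjusted over the list alone. Their median was 0.40 with quantile normalization.

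Other lists were not called in U937. Primary granule proteins (1 higher, 4 lower and 7 not called of 12, 2 and 6 adjusted over the list alone, median -0.45, adjusted p = 0.0714) held CTSG and ELANE (-2.95 ± 0.21), and were called without both U937 arrays numbered 2 (adjusted p = 0.0485). CDK inhibitors (2 higher, 3 lower and 3 not called of 8, 3 and 3 adjusted over the list alone, median 0.01, adjusted p = 0.215) held CDKN1A. Myeloid transcription factors (2 higher, 7 lower and 15 not called of 24, 3 and 7 adjusted over the list alone, median 0.01, adjusted p = 0.834), with a mean of -0.22 against a positive median, held MEIS1 (-2.05 ± 0.20), a partner of HOXA proteins in leukaemia. The protein kinase C family (2 higher, 4 lower and 12 not called of 18, 2 and 4 adjusted over the list alone, median -0.04, adjusted p = 0.705), with the kinase substrate MARCKS at -1.85 ± 0.20, had a median of 0.12 with quantile normalization and a mean 0.10 above other genes. Glycolysis (3 higher, 3 lower and 15 not called of 21, 3 and 3 adjusted over the list alone, median -0.23, adjusted p = 0.969) had a median of 0.01 with centred arrays and a mean 0.15 above other genes. Cholesterol synthesis (2 higher, 0 lower and 16 not called of 18, 2 and 0 adjusted over the list alone, median -0.09, adjusted p = 0.267) had a mean of 0.08 and a median of 0.17 with quantile normalization. Oxidative phosphorylation (0 higher, 1 lower and 23 not called of 24, 0 and 1 adjusted over the list alone, median -0.48, adjusted p = 0.465) was not called (median -0.25 with quantile normalization), although with the replicate block NDUFV2 (-0.95, adjusted p = 0.0014), NDUFA9 (-0.82, adjusted p = 0.00365) and COX6C (-0.72, adjusted p = 0.00764) were lower and the list reached adjusted p = 0.066. Nor were T and NK cell markers (1 higher, 0 lower and 14 not called of 15, 1 and 0 adjusted over the list alone, median 0.02, adjusted p = 0.263), with NCR1 at 0.97 ± 0.22. Also not called were B cell markers (1 higher, 1 lower and 8 not called of 10, 1 and 1 adjusted over the list alone, median 0.05, adjusted p = 0.271), with CD22 at 1.68 ± 0.15 and PAX5 at -0.96 ± 0.20. Erythroid and megakaryocyte markers (1 higher, 0 lower and 12 not called of 13, 1 and 0 adjusted over the list alone, median 0.06, adjusted p = 0.0782) held PPBP (3.46 ± 0.61). Epithelial and fibroblast markers (0 higher, 0 lower and 14 not called of 14, 0 and 0 adjusted over the list alone, median 0.00, adjusted p = 0.379) were not called either. The median change of all genes was 0.13, 0.04 and -0.07 in HL60, THP-1 and U937 as deposited, 0.07, 0.08 and 0.12 with quantile normalization, and 0.08, 0.13 and 0.17 with centred arrays. Of 81 list tests in the 3 lines 48 were called, and 4 with an estimated correlation (27 at unadjusted p under 0.05). None, 0, were called when camera also took the replicate block (14 at unadjusted p under 0.05, lowest adjusted p = 0.229).

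**Figure D1:**
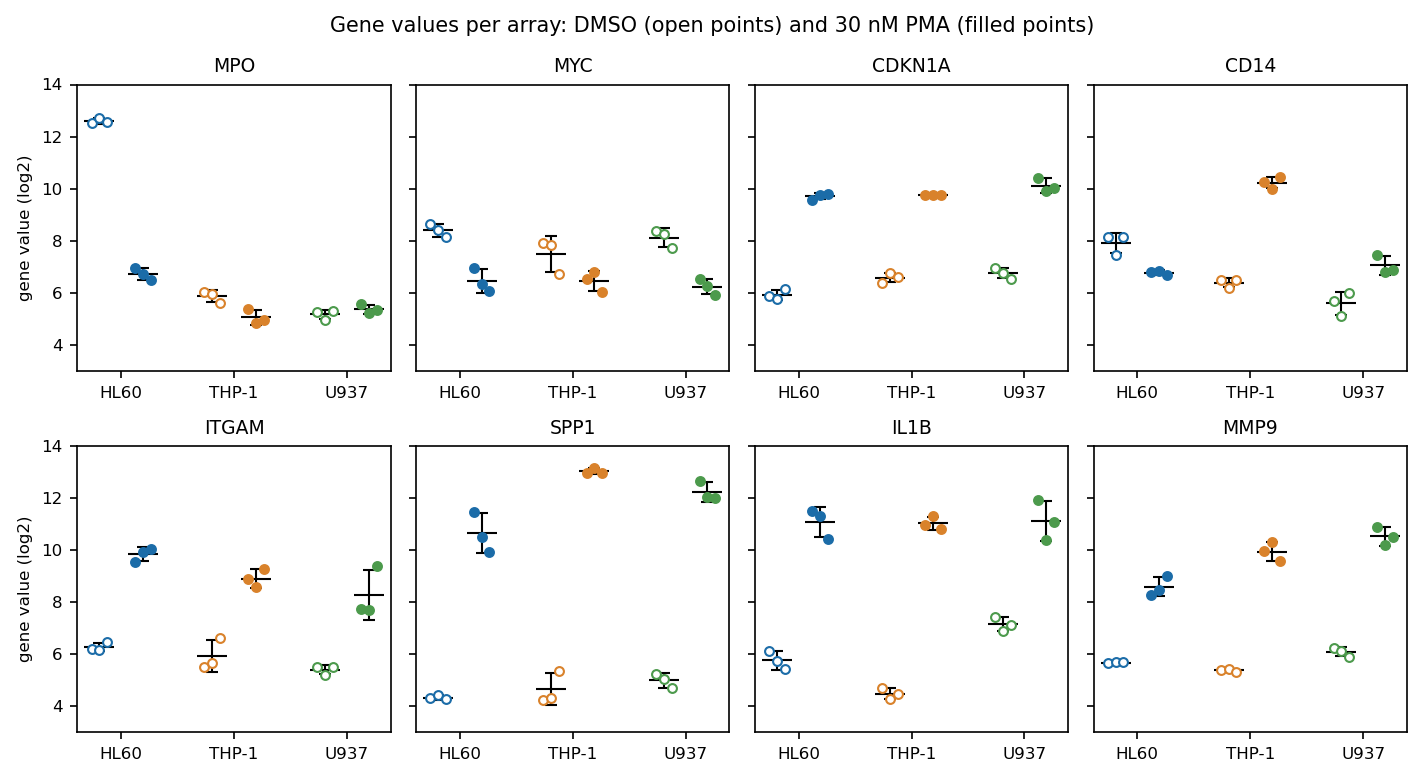
Levels (log2) of MPO, MYC, CDKN1A, CD14, ITGAM, SPP1, IL1B and MMP9 in the 18 arrays, open points for DMSO, filled points for PMA, and bars for mean ± SD of 3 arrays per line and agent. SPP1 went from 4.65 ± 0.62 to 13.03 ± 0.11 in THP-1.

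**Figure D2:**
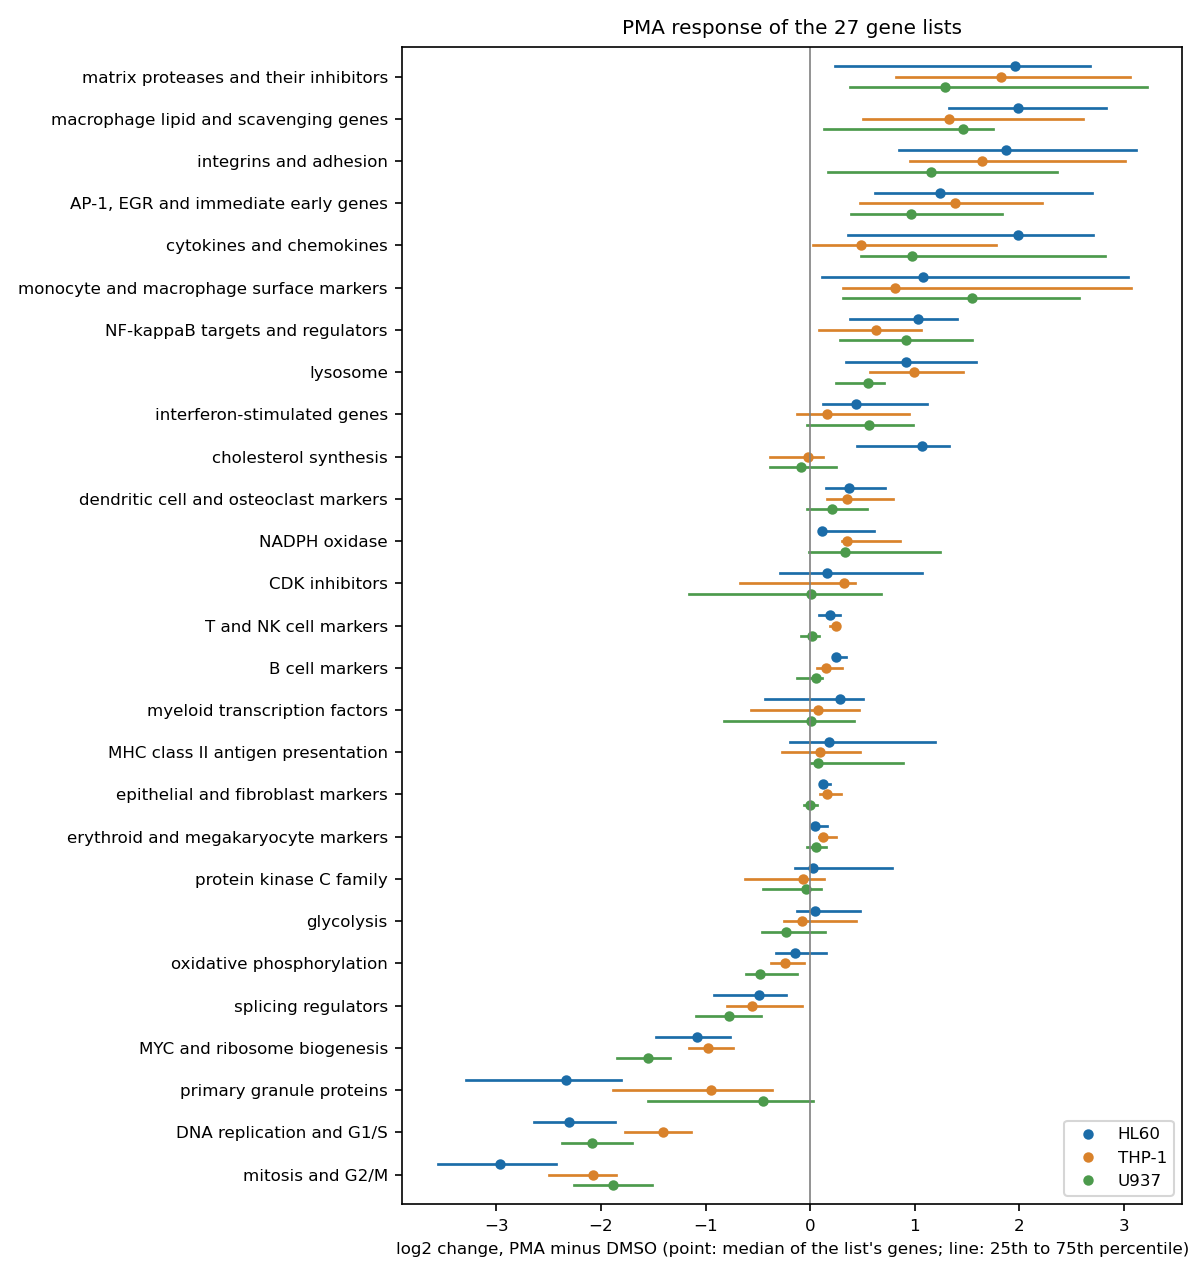
Log2 change with PMA in the 27 gene lists, points for the median and lines for the 25th to 75th percentile of the measured genes of each list, by cell line. The median of mitosis and G2/M genes was -2.97 in HL60, -2.08 in THP-1 and -1.88 in U937.

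The response shared by all 3 lines was led upward by SPP1, RGS1, DCSTAMP (8.57 ± 0.33, 3.77 ± 0.33 and 6.18 ± 0.33) and TM4SF19. CD52, EMP1, A2M (6.70 ± 0.35, 6.79 ± 0.35 and 3.96 ± 0.35) and IL1B rose in all 3 lines. The kinase SGK1 rose by 6.27 ± 0.35, 4.94 ± 0.35 and 4.31 ± 0.35. MMP1 rose by 2.30 ± 0.64, 7.22 ± 0.64 and 5.94 ± 0.64, but was not called in HL60 without PMA 1 (1.85, adjusted p = 0.0659). CTSG (-3.36 ± 0.49, -3.78 ± 0.49 and -5.06 ± 0.49), MYB, PLAC8 and NUCB2 fell in all 3. So did TOP2A (-4.99 ± 0.27, -2.91 ± 0.27 and -2.57 ± 0.27), LAMP5, HSPA4L, ELANE and DLGAP5. SERPINB10 fell by 6.47 ± 0.23, 2.70 ± 0.23 and 0.81 ± 0.23 (U937 adjusted p = 0.0166). The U937 call of SERPINB10 was lost with median polish (adjusted p = 0.104), with the line's arrays alone (adjusted p = 0.0726), without both arrays numbered 2 (adjusted p = 0.0924), and without DMSO 1 (adjusted p = 0.0664), PMA 2 (adjusted p = 0.0638) or PMA 3 (adjusted p = 0.0575).

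In all 3 lines 432 genes rose (10.3 expected of independent lists) and 965 fell (37.7 expected), from 2856 and 3699 called in at least 1 line. The share lower among these 1397 genes was 69.1%, and 57.9% with quantile normalization (849 higher and 1168 lower). The replicate block left 2301 shared, and without U937 PMA 2 757 rose and 1021 fell. Each line has its own DMSO arrays, so the log2 changes share no control. Their Pearson correlation across genes was 0.67 for HL60 and THP-1, 0.67 for HL60 and U937 and 0.69 for THP-1 and U937. Of genes called in both lines of a pair, 1971 changed the same way and 66 oppositely (HL60 and THP-1), 1891 and 76 (HL60 and U937), and 1965 and 44 (THP-1 and U937).

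The PMA effect differed between HL60 and THP-1 in CD14, which fell by 1.13 ± 0.24 in HL60 and rose by 3.84 ± 0.24 in THP-1 (difference -4.98 ± 0.34). MPO fell more in HL60 than in THP-1 (-5.07 ± 0.27). GALNT12 (7.14 ± 0.33), CD226 (6.82 ± 0.34), AQP9 (6.28 ± 0.63), the gluconeogenic enzyme FBP1 (6.10 ± 0.51) and MMP7 (5.54 ± 0.69) had the more positive effect in HL60. MSR1 (-5.22 ± 0.40), MCUB (-5.02 ± 0.65), a subunit of the mitochondrial calcium uniporter, and MMP1 (-4.91 ± 0.90) had it in THP-1. GALNT12 rose in HL60 and fell in THP-1 (-0.71 ± 0.23), as did FBP1 (4.94 ± 0.36 and -1.16 ± 0.36), while ITM2C fell in HL60 (-3.20 ± 0.21) and rose in THP-1 (1.44 ± 0.21). In all, limma called 1265 differences, 794 more positive in HL60 and 471 in THP-1. The replicate block gave 2524, with quantile normalization 2323 and with centred arrays 2161.

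Between HL60 and U937 the PMA effect differed in S100A8 (-6.59 ± 0.79), which fell in HL60 and rose by 1.67 ± 0.56 in U937, and in its partner S100A9 (-4.83 ± 0.96). MPO (-6.08 ± 0.27), SERPINB10 (-5.66 ± 0.33) and MMP8 (-4.62 ± 0.75) also had the more negative effect in HL60. CD226 (7.19 ± 0.34), the sodium pump subunit ATP1B1 (6.60 ± 0.38), CD9 (6.48 ± 0.55), the retinoic acid binding CRABP2 (6.47 ± 0.41) and GALNT12 (6.31 ± 0.33) had the more positive one. ATP1B1 rose in HL60 (5.43 ± 0.27) and fell in U937 (-1.17 ± 0.27), as did CLEC2B (2.42 ± 0.52 and -1.81 ± 0.52). The Fc receptor FCGR1A (-2.40 ± 0.28 and 1.21 ± 0.28) and ADGRE1 (-1.0 ± 0.26 and 2.83 ± 0.26) fell in HL60 and rose in U937. In all, 1257 differences were called, 972 more positive in HL60 and 285 in U937, and 2666 with the replicate block. The share more negative in HL60 was 22.7% as deposited, 42.3% with quantile normalization and 46.3% with centred arrays. Without U937 DMSO 1 639 were higher in HL60, without U937 PMA 2 527 were lower, and without U937 PMA 3 1945 were called, 1681 of them higher.

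Between THP-1 and U937 the PMA effect differed in MSR1 (7.35 ± 0.40), DDIT4L (5.40 ± 0.32), LBH (5.07 ± 0.42), the adenylate cyclase ADCY8 (4.73 ± 0.30) and the lysophosphatidic acid receptor LPAR6 (4.73 ± 0.67), all more positive in THP-1. AQP9 (-6.07 ± 0.63), GPR34 (-5.25 ± 0.62), MMP7 (-5.13 ± 0.69), the chemokine CCL7 (-4.93 ± 0.66) and TM4SF1 (-4.80 ± 0.75) were more positive in U937. The Notch ligand JAG1 rose in THP-1 (2.43 ± 0.37) and fell in U937 (-1.79 ± 0.37), as did ETS1 (2.58 ± 0.21 and -0.78 ± 0.21), and FCGR2A fell in THP-1 (-1.90 ± 0.32) and rose in U937 (1.74 ± 0.32). In all, 774 differences were called, 510 more positive in THP-1 and 264 in U937, and 1649 with the replicate block. The share more negative in THP-1 was 34.1% as deposited, 49.9% with quantile normalization and 50.8% with centred arrays. Without U937 DMSO 2 171 were lower, without U937 PMA 2 1187 were called (481 higher, 706 lower), and without U937 PMA 3 797 were higher.

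Gene lists differed between lines in 19 of 81 tests by camera at the preset correlation, and in 0 with an estimated correlation (5 at unadjusted p under 0.05). Primary granule proteins fell more in HL60 than in THP-1 (adjusted p = 2.8e-07 and adjusted p = 0.271 with an estimated correlation) or U937 (adjusted p = 2.23e-14 and adjusted p = 0.0633 with an estimated correlation), and DNA replication and G1/S genes more in HL60 than in THP-1 (adjusted p = 5.46e-12 and adjusted p = 0.56 with an estimated correlation). Mitosis and G2/M genes also fell more in HL60 than in THP-1 (adjusted p = 1.11e-09 and adjusted p = 0.876 with an estimated correlation) or U937 (adjusted p = 4.5e-21 and adjusted p = 0.271 with an estimated correlation). Cytokines and chemokines rose more in HL60 than in THP-1 (adjusted p = 0.00678 and adjusted p = 0.997 with an estimated correlation), as did cholesterol synthesis genes (adjusted p = 0.00471 and adjusted p = 0.997 with an estimated correlation). For NF-kappaB targets between HL60 and U937, the median difference was 0.00 and the mean -0.14 (adjusted p = 0.0303 and adjusted p = 0.997 with an estimated correlation), and for monocyte markers 0.33 and -0.22 (adjusted p = 0.0297 and adjusted p = 0.997 with an estimated correlation).

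**Figure D3:**
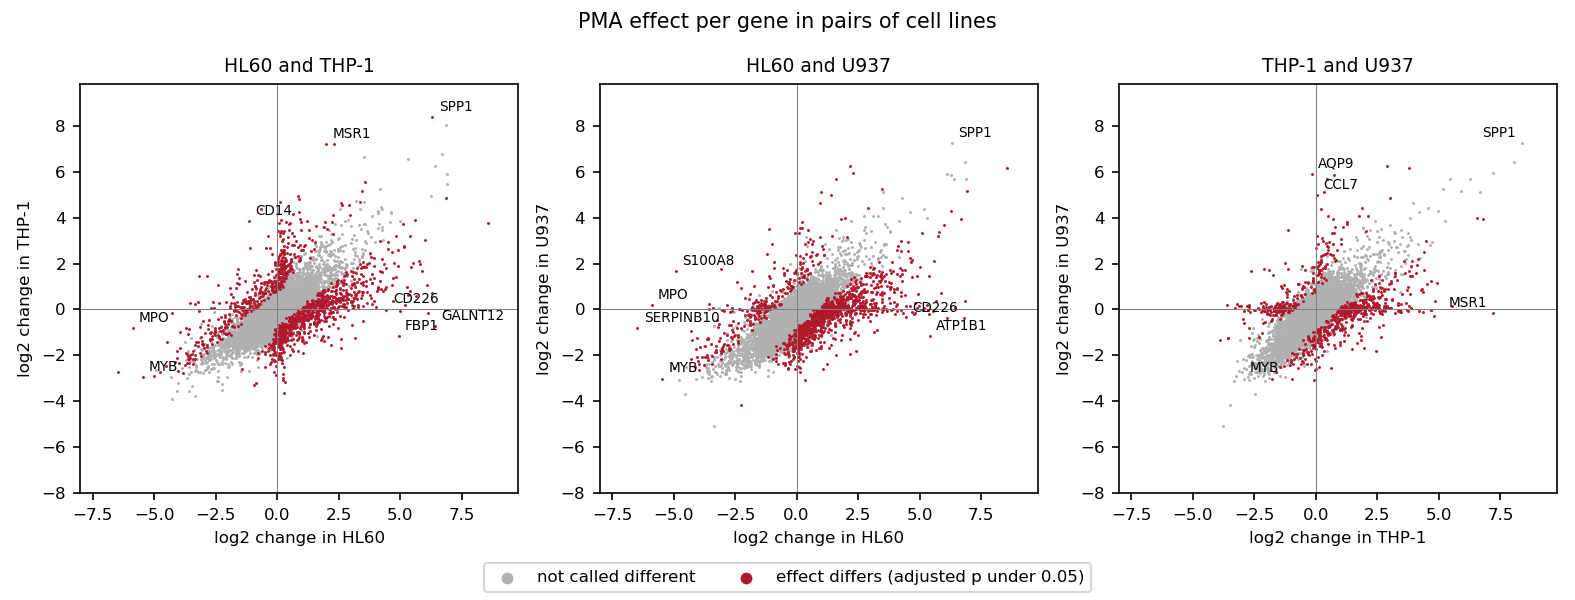
Log2 change with PMA per gene in pairs of cell lines, 1 point per gene, red where the difference between the lines was called by limma. MPO fell in HL60 (-5.88 ± 0.19) and was not called in U937 (0.20 ± 0.19).

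With DMSO alone, MPO stood at 12.60 ± 0.10 in HL60, 5.87 ± 0.22 in THP-1 and 5.17 ± 0.18 in U937. HL60 also exceeded THP-1 in the actin crosslinker FLNA (5.02 ± 0.26), the granule protein BPI (4.84 ± 0.60), ANKRD22 (4.74 ± 0.17) and the cannabinoid receptor CNR2 (4.57 ± 0.30). It had less ADGRL2 (-6.37 ± 0.25), MCOLN2 (-5.65 ± 0.40), RUBCNL (-5.59 ± 0.24) and DYNLT5 (-5.42 ± 0.26). Against U937, HL60 had more SERPINB10 (5.64 ± 0.23), the syntenin SDCBP (5.58 ± 0.29), ZNF141 (4.79 ± 0.24) and CYBB (4.65 ± 0.28). It had less CLEC2B (-6.53 ± 0.52), CLECL1 (-6.28 ± 0.25), MEIS1 (-5.97 ± 0.20) and the cytidine deaminase APOBEC3B (-5.37 ± 0.32). THP-1 exceeded U937 in the carbonic anhydrase CA2 (7.12 ± 0.37), SDCBP (6.21 ± 0.29) and ADGRL2 (6.2 ± 0.25), and had less CLEC2B (-7.23 ± 0.52), the succinate receptor SUCNR1 (-6.46 ± 0.40) and IL2RG (-6.34 ± 0.42).

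With DMSO, limma called 2698 genes between HL60 and THP-1 (943 higher and 1755 lower in HL60, MPO among the higher), 3715 between HL60 and U937 (628 and 3087) and 4269 between THP-1 and U937 (1227 and 3042). These levels cross arrays that appear to have been normalized in separate sets, and the scaling moved the split. The shares lower were 65.0%, 83.1% and 71.3% as deposited, 52.0%, 55.5% and 50.7% with quantile normalization, and 46.7%, 51.8% and 50.9% with centred arrays. The median of all genes was 0.05, -0.23 and -0.31 as deposited, 0.09, 0.04 and -0.08 with quantile normalization, and 0.14, 0.10 and -0.07 with centred arrays. Without both U937 arrays numbered 2, 7078 genes were called between THP-1 and U937, 1280 higher and 5798 lower in THP-1 (81.9% lower). Without HL60 DMSO 2 616 genes were higher in HL60 than in THP-1. Without U937 DMSO 1 1985 were lower in HL60 and 1840 in THP-1 than in U937.

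The largest exon usage call named in HL60 was in TSC22D1, a transcription regulator with several promoters. Probe set 3512308 rose about 7.03 ± 0.52 log2 units more than the rest of the gene (adjusted p = 3.75e-27, and adjusted p = 2.68e-08 by the splicing index). Its level went from 3.33 ± 0.34 to 12.00 ± 0.17, and the gene rose by 1.94. In MYB, probe set 2926804 changed by 0.44 while the gene fell by 5.47, a difference of 6.25 ± 0.45 (adjusted p = 2.69e-27, and adjusted p = 4.4e-07 by the splicing index). The diffSplice p-values treat the probe sets of a gene as replicates. The DMSO levels of TSC22D1 3512308, PHLDA1, H2AC6, COL22A1, SPOCD1, FCMR, MAP3K7CL, MMP19, VWF, KIR3DL3, PZP, CD44 3326694 and MBNL1 2648174 probe sets lay below 5.17 in at least 1 line, so their differences are approximate. PHLDA1 3462831 (5.61 ± 0.40) and STMN1 2402475 (5.40 ± 0.71) were also positive. CSF1 2351082 (-5.54 ± 0.45), the aromatase gene CYP19A1 3624126 (-5.49 ± 0.55), TNFAIP8L3 3623966 (-5.42 ± 0.45) and GALNT12 3181602 (-5.36 ± 0.45) rose less than their genes. In all, diffSplice called 4869 probe sets in 2074 genes, 2602 with a positive and 2267 with a negative difference, and the splicing index 6050, with 4126 called by both. Among simulated HL60 probe sets with nothing planted, diffSplice called 484 and the splicing index 3. With the replicate block 8256 were called, 3182 without HL60 DMSO 2, and 692 in genes with a change within -1 to 1.

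In THP-1, exon usage changed most in DDIT4L, whose probe set 2779537 changed by 0.50 while the gene rose by 5.54 (difference -6.04 ± 0.43). In the collagen gene COL22A1, probe set 3155639 went from 3.87 ± 0.65 to 9.75 ± 0.16 while the gene of 51 probe sets changed by 0.53 (5.41 ± 0.31, adjusted p = 3.53e-49, and adjusted p = 1.82e-06 by the splicing index). The histone gene H2AC6 2899167 (5.68 ± 0.65), PHLDA1 3462832 (5.43 ± 0.40), SPOCD1 2404776 (4.69 ± 0.44), the IgM receptor FCMR 2452992 (4.67 ± 0.47) and MAP3K7CL 3917262 (4.47 ± 0.49) had positive differences. CYP19A1 3624126 had a negative one (-4.45 ± 0.55). In all, 2623 probe sets in 1393 genes were called (1509 positive, 1114 negative) by diffSplice and 3143 by the splicing index, 1997 by both. Simulated arrays with nothing planted gave 518 calls by diffSplice. Fitted with the replicate block 5176 were called, without THP-1 DMSO 1 1435, without DMSO 2 1454, without PMA 1 1392 and without PMA 2 1670. In genes with a change within -1 to 1 522 were called.

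In U937, the largest exon usage call named was in the complement receptor C5AR1. Its probe set 3837258 changed by 0.43 while the gene rose by 4.62 (difference -5.02 ± 0.43), and may be one that does not follow its gene. MMP7 3388685 (-4.92 ± 0.65), RASGRP3 2476675 (-4.73 ± 0.56) and A2M 3443393 (-3.95 ± 0.61) lagged their genes likewise. MMP19 3457279 (4.49 ± 0.44), VWF 3441726 (4.33 ± 0.57), the gene of von Willebrand factor, SPOCD1 2404776 (4.25 ± 0.44) and KIR3DL3 4052958 (3.98 ± 0.47) rose more than theirs. In all, 1766 probe sets in 1017 genes were called (952 positive, 814 negative) by diffSplice and 2158 by the splicing index, 1264 by both. In U937 simulated arrays with nothing planted gave 527 calls by diffSplice. With the replicate block 4357 were called, without U937 DMSO 1 945, without DMSO 2 931 and without PMA 1 1047, and without PMA 3 1303 were negative. In genes with a change within -1 to 1 285 were called.

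In all 3 lines, probe set 2926804 of MYB differed by 6.25 ± 0.45, 3.52 ± 0.45 and 3.54 ± 0.45. It is the lowest-numbered of 18, and the other 17 fell at least 2-fold in each line. PHLDA1 3462832 (4.86 ± 0.40, 5.43 ± 0.40 and 3.84 ± 0.40), SPOCD1 2404776 (4.58 ± 0.44, 4.69 ± 0.44 and 4.25 ± 0.44) and MMP19 3457279 (4.39 ± 0.44, 3.35 ± 0.44 and 4.49 ± 0.44) rose more than their genes. EGR2 3291603 (-5.34 ± 0.52, -2.77 ± 0.52 and -3.38 ± 0.52), SPP1 2735055 (-4.49 ± 0.64, -3.38 ± 0.64 and -3.60 ± 0.64) and A2M 3443393 (-3.90 ± 0.61, -3.43 ± 0.61 and -3.95 ± 0.61) rose less. Probe set 3443487 of PZP, a close paralog of A2M, differed by 3.78 ± 0.44, 4.15 ± 0.44 and 3.86 ± 0.44. Its own change was 6.18, 6.78 and 4.70, near that of A2M (6.70, 6.79 and 3.96), while PZP as a gene changed by 0.83, 0.86 and 0.31 and was not called in U937 (adjusted p = 0.304). In all, 428 probe sets in 285 genes were called the same way in all lines, 278 positive and 150 negative (0.189 expected of independent lists). By both tests 349 in 232 genes were, and 983 with the replicate block. In genes with a change within -1 to 1 only 29 were shared. Without single arrays the count fell to 276, 253 and 282 (THP-1 DMSO 1, DMSO 2 and PMA 1) and to 260, 274 and 275 (U937 DMSO 1, DMSO 2 and PMA 1).

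**Figure D4:**
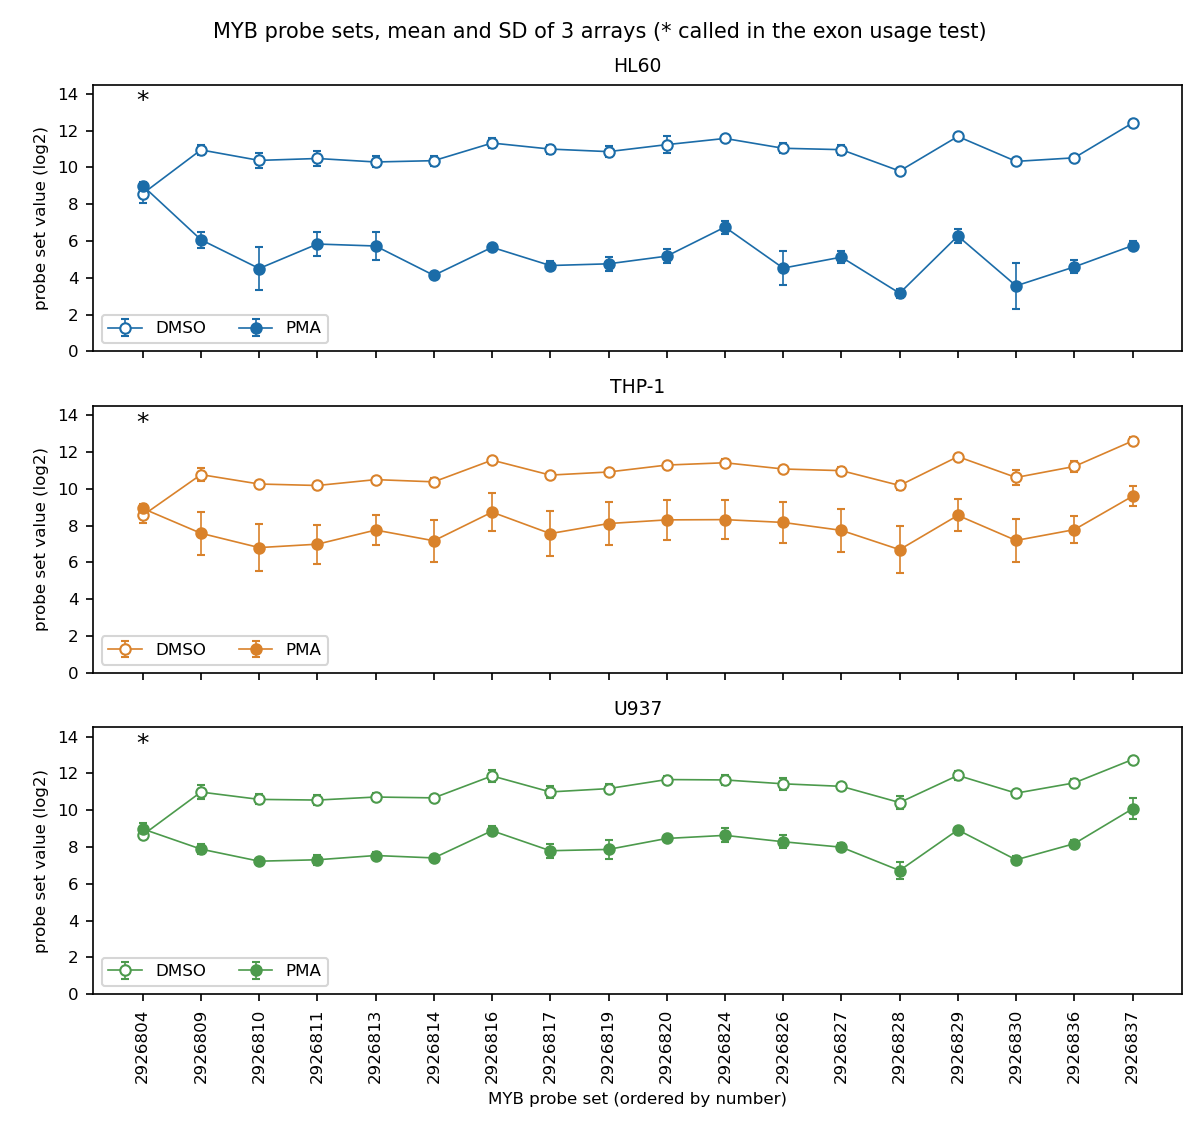
Levels (log2) of the 18 tested MYB probe sets in order of their numbers, mean ± SD of 3 arrays with DMSO and with PMA, a panel per line and a star at the probe set called. Probe set 2926804 in HL60 went from 8.57 ± 0.49 to 9.0 ± 0.19, and the others fell.

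Of the 10 genes fixed for the exon usage test, CD44 was called in HL60 at probe set 3326686 (-1.32 ± 0.38, adjusted p = 0.0236) and in THP-1 at 3326694 (-2.30 ± 0.38, adjusted p = 2.69e-06). The HL60 call of CD44 was lost with no filter on dim probe sets (adjusted p = 0.0965), with the line's 6 arrays alone (adjusted p = 0.0553), and without DMSO 1 (adjusted p = 0.134), DMSO 2 (adjusted p = 0.069), DMSO 3 (adjusted p = 0.0918), PMA 1 (adjusted p = 0.128) or PMA 2 (adjusted p = 0.0546). FN1, the fibronectin gene, was called in THP-1 at 2598376 (-3.39 ± 0.96, adjusted p = 0.036). That of FN1 was lost with no filter (adjusted p = 0.0846), above the 50th percentile (adjusted p = 0.0507), and without THP-1 DMSO 1, 2 or 3 (adjusted p = 0.134, 0.207 and 0.111) or PMA 1, 2 or 3 (adjusted p = 0.138, 0.171 and 0.113). MBNL1, itself a splicing regulator, was called at 2648174 in HL60 (-1.61 ± 0.36, adjusted p = 0.00127) and with the opposite sign in U937 (1.34 ± 0.36, adjusted p = 0.0342), a difference between lines that was not tested. The splicing index called MBNL1 in neither (adjusted p = 0.0583 and 0.218). In U937 MBNL1 was also lost with the line's arrays alone (adjusted p = 0.133), without both arrays numbered 2 (difference 0.73, adjusted p = 1), and without DMSO 2 (difference 0.80, adjusted p = 1), PMA 1 (adjusted p = 0.209) or PMA 2 (adjusted p = 0.106). In PTPRC, PKM, TPM1, ACTN1, VCL, BCL2L1 and CD33, diffSplice called 0 probe sets (lowest adjusted p = 0.0562, in TPM1 in HL60) and the splicing index 1, in PTPRC in HL60.

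Among 67 tested genes with known regulated exons, CD44 and CSF1 included, 24 had a call in HL60 (35.8% against 17.3% of all tested genes). In THP-1 18 did (26.9% against 11.6%), and in U937 7 did (10.4% against 8.49%). Fisher exact adjusted p was 0.000768, 0.00108 and 0.51 in that order. Of 10000 random lists matched in probe-set number alone, the median held 15, 10 and 7 such genes (permutation adjusted p = 0.0126, 0.0126 and 0.602). Calls gather in changed genes, which may account for this.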

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

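The scaling test below, the correlation between array sets, the block for 2 array sets and leaving out both U937 arrays numbered 2 were chosen only after the result was seen, as were the list tests between lines. Some results were set apart because the effect of PMA differed between lines under the same contrast. By that reason stood the 1265 genes whose effect differed between HL60 and THP-1, the 1257 between HL60 and U937 and the 774 between THP-1 and U937. Of 100 splits drawn of the arrays of a pair of lines, the real one included, 8, 5 and 10 gave at least as many calls (highest other 5252, 3645 and 7506). In the 7, 4 and 9 other splits with as many, most arrays of 1 treatment were exchanged between the lines, so that differences in level between the lines entered the contrast. Their high counts point to that structure of the samples, and so these splits do not decide on chance.

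By the same reason stood single genes. Between HL60 and THP-1 these were GALNT12 (7.14), CD226 (6.82), AQP9 (6.28), FBP1 (6.10), MMP7 (5.54), MSR1 (-5.22), MPO (-5.07), MCUB (-5.02), CD14 (-4.98) and MMP1 (-4.91). Between HL60 and U937 they were CD226 (7.19), ATP1B1 (6.60), CD9 (6.48), CRABP2 (6.47), GALNT12 (6.31), S100A8 (-6.59), MPO (-6.08), SERPINB10 (-5.66), S100A9 (-4.83) and MMP8 (-4.62). Between THP-1 and U937 they were MSR1 (7.35), DDIT4L (5.40), LBH (5.07), ADCY8 (4.73), LPAR6 (4.73), AQP9 (-6.07), GPR34 (-5.25), MMP7 (-5.13), CCL7 (-4.93) and TM4SF1 (-4.80).

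Gene lists also stood apart by a difference between lines, each with camera's adjusted p at the preset correlation, and 0 of them with an estimated correlation (5 at unadjusted p under 0.05). They were primary granule proteins (HL60 and THP-1 adjusted p = 2.8e-07, HL60 and U937 adjusted p = 2.23e-14, THP-1 and U937 adjusted p = 0.0102), DNA replication and G1/S (adjusted p = 5.46e-12, 0.00157 and 4.08e-05 in that order) and mitosis and G2/M (adjusted p = 1.11e-09, 4.5e-21 and 0.0027). Cytokines and chemokines differed between HL60 and THP-1 (adjusted p = 0.00678) and THP-1 and U937 (adjusted p = 0.00157), and NF-kappaB targets and regulators between HL60 and U937 (adjusted p = 0.0303) and THP-1 and U937 (adjusted p = 0.00471). Between HL60 and U937, monocyte and macrophage surface markers (adjusted p = 0.0297), macrophage lipid and scavenging genes (adjusted p = 0.0272) and NADPH oxidase (adjusted p = 0.0303) differed. Integrins and adhesion (adjusted p = 0.00829) and MYC and ribosome biogenesis (adjusted p = 0.0142) differed between THP-1 and U937, and cholesterol synthesis between HL60 and THP-1 (adjusted p = 0.00471).

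Probe sets without a single gene symbol stood apart because they changed and cannot be named. Higher with PMA were 456 with several symbols and 752 with none in HL60, 281 and 340 in THP-1, and 269 and 267 in U937. Lower were 879 and 1373, 618 and 906, and 721 and 1030.

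The excess of lower genes in U937 bears on the differences with that line, 75% of 3572 called genes being lower. The low level of the U937 PMA 2 array may account for much of it. The share was 55.7% of 2973 without both arrays numbered 2, and 49.7% without U937 PMA 2 alone. Scaling of the arrays, a test chosen after the result was seen, gave 51.7% with quantile normalization. That normalization evens out the array medians, so this test cannot tell scaling from a true fall of many RNAs in U937. Such a fall, for example in cells that stop dividing, stays open and untested.

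Within treatments the arrays fell into 2 sets that cut across the lines, and their first principal component held 58.2% of the variance of the deviations. The sign of PMA minus DMSO was the same in both sets for 100%, 99.9% and 99.6% of the genes called in HL60, THP-1 and U937, but called genes were chosen for a steady change, so these shares decide nothing. Over all genes, PMA minus DMSO correlated between the sets at 0.944, 0.869 and 0.824, which argues against a PMA effect that belongs to 1 set. Separate cultures or days of work could both form such sets and were not tested.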

How the results depend on the processing

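Of the varied counts, 204 stayed within 1.5-fold in size, 110 of them on leaving out 1 array, and 50 did not, which does not say whether the genes called were the same. No named gene (0) was reversed. The cause was not tested for any change below. A replicate block, which pairs the DMSO and PMA arrays of a number, raised most counts: genes in HL60 5575, THP-1 5646 and U937 5403, differences 2524 (HL60 and THP-1), 2666 (HL60 and U937) and 1649 (THP-1 and U937), shared genes 2301, exon usage in HL60 8256, THP-1 5176 and U937 4357, and shared exon usage 983. Of the list calls this block changed 1, that of dendritic cell and osteoclast markers in HL60 (adjusted p = 0.0546). The array set block, chosen after seeing the data, gave 2017 differences for HL60 and U937 and 1176 for THP-1 and U937, and exon usage calls of 7539, 4478 and 3715, with 869 shared. Quantile normalization raised the differences to 2323 (HL60 and THP-1) and 1394 (THP-1 and U937) and the DMSO comparison of HL60 and THP-1 to 4201. Centred arrays gave 2161, 1330 and 4430 for these. Only the arrays compared gave 2052 differences for HL60 and THP-1, and genes above the 30th percentile 449 for THP-1 and U937. Without both U937 arrays numbered 2, the DMSO comparison of THP-1 and U937 rose to 7078 and exon usage in U937 fell to 953. Exon usage fell to 692, 522 and 285, and to 29 shared, in genes with a change within -1 to 1. Above the 50th percentile THP-1 had 1649, and the 6 arrays of U937 alone 1023. Of gene lists, 48 fell to 4 with an estimated correlation, and to 0 when the replicate block was added (14 at unadjusted p under 0.05).

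Leaving out each array in turn, with the pooled spread of limma where 2 arrays remained, gave 3002 to 3495 genes in HL60, 2576 to 3683 in THP-1 and 2568 to 4042 in U937. Differences ranged from 902 to 1201 (HL60 and THP-1), 887 to 1945 (HL60 and U937) and 560 to 1187 (THP-1 and U937), and the DMSO comparisons from 1960 to 2585, 2516 to 3512 and 2949 to 3815 in that order. Shared genes ranged from 1101 to 1778. Exon usage ranged from 3182 to 4232 in HL60, 1392 to 3070 in THP-1 and 931 to 2544 in U937, and shared exon usage from 253 to 477.

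The values were log2 already, so adding 16 before the logarithm was not applicable. A replicate block for the lines with DMSO gives no value, because each block lies within 1 line. Signal over background was not used here, so probe sets that are not detected were removed only by their mean level.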

Other observations

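Families of genes by the root of their symbol were tested only after the result was seen, as was the block for array sets. Of 627 tests of 209 families camera called 97, but 0 with an estimated correlation (7 at unadjusted p under 0.05), so the counts of members below stand for themselves. Of genes with the root MCM 8 of 10 were lower in each of HL60, THP-1 and U937, with medians of -2.41, -1.47 and -2.19 (-2.45, -1.36 and -1.91 with quantile normalization). For MCM, adjusted p = 3.25e-10, 1.07e-05 and 3.79e-09, and adjusted p = 0.998 in each line with an estimated correlation. Nucleoporins (NUP) were lower in 9, 11 and 15 of 21, centrosomal proteins (CEP) in 15, 18 and 16 of 30, and RAD repair genes in 8, 9 and 9 of 15. Of 413 zinc finger genes of the ZNF family, 150 were lower and 7 higher in THP-1, with a median of -0.51 (-0.44 with quantile normalization and -0.42 with centred arrays). For ZNF in THP-1, adjusted p = 3.25e-10, and adjusted p = 0.998 with an estimated correlation. In HL60 70 ZNF genes were lower and 18 higher, and in U937 99 and 3. Metallothioneins (MT) were lower in 0, 6 and 1 of 15, with a median of -0.68 in THP-1 (-0.61 with quantile normalization). Dual-specificity phosphatases (DUSP) were higher in 10, 8 and 8 of 22, CCL chemokines in 7, 3 and 8 of 19, TNF receptors (TNFRSF) in 10, 7 and 6 of 20, and ITGB-root genes in 5, 6 and 3 of 11.

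Exon usage calls gathered in genes whose level changed, and the test of array scaling and the array set block were chosen only after the result was seen. Of the calls, 74.2%, 65.0% and 70.7% in HL60, THP-1 and U937 lay in genes changed at least 2-fold, which made up 20.7%, 18% and 19.8% of those tested. Probe sets that do not follow their gene would mostly oppose its change, and 60.1%, 65.1% and 67.5% did. These shares lie between the bounds set beforehand, so such probe sets cannot be told from another promoter or exon taken up with PMA. Of those opposing, 58.6%, 66.0% and 76.9% moved by under 0.5 log2. Low signal may add calls too. The called probe sets lay near the others of their genes in mean level (gap -0.20, -0.34 and -0.23 log2). These are means over 18 arrays without the dimmest probe sets. TSC22D1 3512308 was at 3.33 with DMSO in HL60, so the gap excludes nothing.

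Array splits were run for differences above and counts below. With 10 per comparison, too few for a share under 0.05, 1, the real one, gave as many calls in each. For genes with PMA the real counts were 3745, 3668 and 3572 in HL60, THP-1 and U937, and for the lines with DMSO 2698, 3715 and 4269, with 0 as the highest other in all 6. For exon usage the real counts were 4869, 2623 and 1766 and the highest others 1482, 1913 and 1486, in splits that follow the array sets. Of 100 splits drawn, 1 gave as many shared genes as 1397 (highest other 0). Mixing PMA and DMSO widens the spread, so chance stays open. For shared exon usage 2 of 100 gave as many as 428 (highest other 747), so chance and array sets stay open. In the split with 747 (0 shared genes), 8 of the 9 arrays in the first groups were of 1 array set.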
